A study of Homo sapiens with 2 samples.

How the data were processed

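RNA of 2 samples labelled as U87 cells, 1 with a non-target siRNA and 1 with an siRNA against FOXM1, was measured on 1 array each. Per the labels' protocols, total RNA was isolated with TRIZOL after transfection with a lipid reagent, checked on a Bioanalyzer and turned into biotin-labelled cRNA with a 3' IVT kit, which starts from the poly-A tail and so reports mainly the 3' end of transcripts. Per the submitters' processing notes the values were made with MAS5, the Affymetrix algorithm that corrects for mismatch probes and scales each array as a whole; its version and settings are not given in the sources used here. The deposited values are linear signal intensities, 1 per probe set and array, for 54675 probe sets. The trimmed mean of the intensities, leaving out 2% at each end, was 500.07 on both arrays, so the deposited intensities had been scaled to a common target. Global scaling of this kind assumes that the mean signal is equal in both samples. The deposited values held no detection calls and no replicate arrays were analysed. The number of arrays limits the precision: with 1 array per group there is no SD between samples, no p-value and no count of significant genes.

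Probe sets were named through the platform annotation, which listed 42898 probe sets, 41097 of them with 1 gene symbol and 1801 with several; 11777 probe sets were not in it, most control probe sets included. Symbols were brought up to date through the gene ID where possible (99.9% of probe sets, gene table of assembly GRCh38.p14), giving 19775 genes. Probe sets with several symbols named no gene. No genome build underlies the array values, so no coordinates are given. One of the 20 genes fixed as linked to FOXM1 and some members of the fixed lists had no probe set with a single symbol and were not analysed here. FOXM1 had 1 probe set, of a kind whose probes can match several transcripts.

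Log2 differences are the array labelled FOXM1 siRNA minus the array labelled non-target siRNA, on the deposited scaling. The floor of each array was the 90th percentile of the signals of 135 probe sets for olfactory receptor genes, 60.8 and 77.7 on the arrays labelled non-target and FOXM1 siRNA. Lower values were raised to the floor before log2. A gene was represented by its probe set with the highest mean log2 signal and was detected if that probe set lay above the floor on at least 1 array: 11395 genes on both arrays and 2470 on 1 array. For the latter a fold is a bound, written as "at least", against the floor of the dimmer array; 416 of them, whose bound was under 1, were given no fold. Counts use a 2-fold threshold. Different probe sets of a gene do not always agree, so the SD of their log2 differences, or the value of another probe set, is given for named genes with an SD above 1.5 and for some others.

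The 36 gene lists, the rule for named genes, the floor and the alternatives, except those named below, were fixed before the data were examined. Named genes were FOXM1, the 12 genes with the largest difference in each direction above the floor on both arrays whose other probe sets above both floors, if any, all went the same way, the 5 largest bounds per direction, 20 genes linked to FOXM1 in earlier work, and from each list up to 4 members (up to 2 where the list lay inside the random range), in all 140 genes. The median of each list was set against 10000 random lists of the same size, drawn from the detected genes within 20 bins of mean signal. That percentile describes these 2 arrays and is not a p-value. Counts of list members are of those detected. The lists overlap in part and are not independent.

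On simulated data for this comparison, with the real mean signals and the probe set SD of 0.46 as noise, 99.0% of 100 genes changed 4-fold and 100% of 100 genes changed 8-fold were recovered beyond 2-fold among 13142 genes, and 2.73% of unchanged genes passed that threshold. A simulated list of 40 genes shifted by 0.8 lay above all random lists, and 5 of 100 unshifted lists lay outside the central range. The simulated noise was independent and of equal size for all genes, and the unshifted lists were drawn at random. These shares therefore check the calculation and do not calibrate the counts or percentiles of the real arrays. The alternatives were median centring, quantile and loess scaling, no floor, a floor 2 times as high, the median of a gene's probe sets, leaving out probe sets with IDs ending in _x_at or _s_at, a pseudocount of 50, a 1.5-fold threshold, the mean over list members and list members above the floor on both arrays. Scaling to the hybridisation controls and a common floor were added after seeing the data. The 18 hybridisation control probe sets, bacterial and phage sequences added in equal amounts, had a median log2 difference of 0.30, and the 24 poly-A labelling control probe sets one of -0.08. Quantile and loess scaling used limma 3.58.1 in R 4.3.3 (loess span 0.3); the rest used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.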

Results

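Gene expression was compared between 2 samples labelled as U87 cells, an established human glioblastoma line. One sample was labelled as transfected with a non-target control siRNA and the other with an siRNA against FOXM1, a forkhead transcription factor that activates genes of the G2 and M phases of the cell cycle. RNA was collected 48 hours after transfection and hybridised to 1 array each, so each group holds 1 sample and no test between the conditions was possible. The study was set up to ask which transcripts differ after FOXM1 knockdown; the values below compare the 2 arrays as labelled. All values below are differences between these 2 arrays, with no replicate check. The only error available comes from within the 2 arrays. The log2 differences of 2 probe sets of one gene differed from each other with an SD of 0.65. This was taken over 5476 genes with at least 2 probe sets above the floor on both arrays. It corresponds to an SD of 0.46 per probe set. Of 54675 probe sets, 53.2% lay above the floor on the array labelled non-target siRNA and 50.5% on the array labelled FOXM1 siRNA. These correspond to 12814 and 12446 genes. A total of 13865 genes were detected on at least 1 array.

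FOXM1 itself differed little. Its single probe set read 1520 on the array labelled non-target siRNA and 1343 on the array labelled FOXM1 siRNA. The log2 difference of -0.18, or 0.884 times the control level, is smaller than the SD of 0.46 per probe set. The target transcript therefore gave no check of the labels at this precision, and all directions below are those of the 2 arrays as labelled. A second locus differed far more. The 9p21 genes CDKN2A and CDKN2B, which encode inhibitors of cyclin-dependent kinases, and MTAP, an enzyme of methionine salvage, were fixed as a list because this region is deleted in many gliomas. CDKN2A read 3467 on the array labelled non-target siRNA and 421 on the array labelled FOXM1 siRNA in its brightest probe set, an 8.24-fold difference, and a further probe set of it differed by 20.5-fold. MTAP was 619 against 76.3 and CDKN2B 350 against 31.8, below the floor on the array labelled FOXM1 siRNA, so that they were at least 7.96-fold and at least 4.50-fold lower there. The other CDKN2B probe set lay below the floor on both arrays. U87 cells are known to lack these genes through a homozygous deletion. Their transcripts on the array labelled non-target siRNA argue against RNA of such cells on both arrays. In the results below, an effect of the siRNA therefore cannot be told apart from a difference between the cells.

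The difference between the arrays was broad. With 1 probe set per gene, 2218 genes were at least 2-fold higher and 2132 at least 2-fold lower on the array labelled FOXM1 siRNA, together 31.4% of detected genes. A difference of at least 8-fold was found for 379 genes in the higher and 154 in the lower direction. The split depended on the scaling: with the hybridisation controls set equal, 1567 genes were higher and 3200 lower, and the median of all genes moved from 0.01 to -0.29 on the log2 scale. Over the 11395 genes above the floor on both arrays, log2 signals of the 2 arrays correlated with a Pearson r of 0.82 (across genes, which are not independent replicates). Among 2202 genes with a 2-fold or larger difference and at least 1 further detected probe set, the others went the same way in 90.4% (95% Wilson interval 89.1 to 91.6%, which covers counting error only) and were themselves 2-fold or more different in 52.7%.

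**Figure D1:**
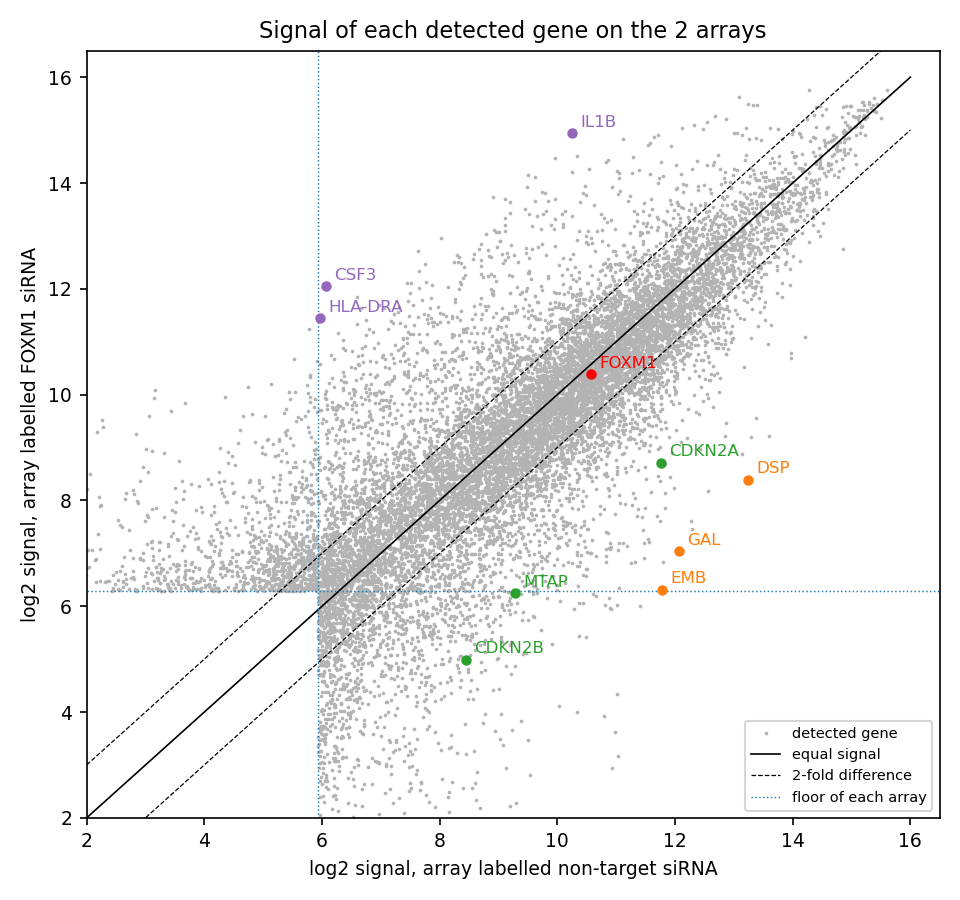
Log2 signal of each of the 13865 detected genes on the array labelled non-target siRNA (x axis) and on the array labelled FOXM1 siRNA (y axis), each grey point 1 gene. The solid line marks equal signal, the dashed lines a 2-fold difference and the dotted lines the floor of each array; FOXM1 (red) lies near the line of equal signal while CDKN2A, MTAP and CDKN2B (green) lie below it.

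Among the genes with the largest differences on the higher side were those of cytokines, matrix and surface proteins. CSF3, a granulocyte growth factor, was 63.6-fold higher on the array labelled FOXM1 siRNA (67.1 against 4263). HLA-DRA, a chain of MHC class II, was 44.7-fold higher, TMPRSS15 38.0-fold and the bradykinin receptor gene BDKRB1 33.9-fold. PTPRN2, the noncoding RNA MIR100HG, the collagen gene COL8A1, the proteoglycan gene SRGN, the metalloprotease gene ADAM12, SIGLEC15, the adhesion molecule gene CLMP and the cytokine gene IL1B followed, at 31.5- to 25.7-fold. For SRGN and IL1B, the log2 differences of 2 probe sets each had SDs of 0.02 and 0.16, whereas the 5 probe sets of ADAM12 had an SD of 1.91 and the other probe set of COL8A1 gave 0.65. On the lower side, the adhesion protein gene EMB was 44.3-fold lower (3519 against 79.5), the neuropeptide gene GAL 32.6-fold, the forkhead gene FOXF2 31.0-fold, the desmosome gene DSP 28.9-fold and the transcriptional coactivator gene CITED1 28.6-fold. LGALSL, CENPV, NUP62CL, AUTS2, RASGEF1A, LRATD2 and the heparan sulfate sulfotransferase gene HS6ST2 followed, at 26.2- to 20.6-fold. Other probe sets of several of these genes differed less, with SDs over probe sets of 3.07 for LRATD2, 2.97 for NUP62CL, 2.56 for AUTS2, 2.05 for RASGEF1A and 1.58 for HS6ST2. With the median of a gene's probe sets LRATD2 was at -2.20 and AUTS2 at -0.40 on the log2 scale, and without _x_at and _s_at probe sets NUP62CL was at -0.35, the last 2 values being under 2-fold. EMB and GAL each had a further probe set below the floor on the array labelled FOXM1 siRNA, and the SDs over 2 probe sets were 3.84 and 3.78. With that floor in place of their signals, these further probe sets gave log2 differences of only -0.04 and 0.32. With the median of probe sets EMB was at -2.76 and GAL at -2.35. Among genes above the floor on 1 array only, TCIM was higher by at least 5.32 on the log2 scale, DOCK10 at least 26.9-fold, C10orf90 at least 26.2-fold, LINC01119 at least 21.8-fold and NAV3 at least 21.2-fold higher. In the same class MAP7 had a log2 difference of at most -5.13, SLC16A10 was at least 26.9-fold, MTARC1 and BEND4 at least 26.5-fold and ALDH1A2, a retinoic acid synthesis enzyme, at least 26.0-fold lower. The SDs over probe sets were 3.15 for ALDH1A2 and 1.57 for SLC16A10.

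DNA replication and repair genes were lower as groups on the array labelled FOXM1 siRNA, and most mitotic genes differed by less than 2-fold. Of the 56 mitotic genes known as FOXM1 targets, 4 were at least 2-fold lower, 1 at least 2-fold higher and 51 differed by less than 2-fold. Their median log2 difference of -0.31 lay at percentile 4.42 of 10000 random lists matched on signal, inside the central range of -0.35 to 0.17, and 42 members lay below 0. Without _x_at and _s_at probe sets the median of the mitotic list was -0.43 at percentile 1.37, below the random range. The spindle checkpoint kinase gene TTK was 2.95-fold lower and the kinetochore gene NUF2 2.62-fold lower. All 50 measured DNA replication and G1/S genes were above the floor on both arrays, and 16 of them were at least 2-fold lower and none higher. The median of -0.65 (1.57-fold lower) lay below all 10000 random lists. The replication kinase gene CDC7 was 6.47-fold lower, the GINS complex gene GINS1 4.24-fold, the licensing inhibitor gene GMNN 3.92-fold and the polymerase gene POLA1 3.31-fold. Of 33 homologous recombination and Fanconi genes, 10 were at least 2-fold lower and 2 higher, with a median of -0.72 at percentile 0.085. EXO1, a nuclease of resection, was 4.12-fold lower, the helicase gene BLM 3.73-fold, the nuclease gene MRE11 3.70-fold and the checkpoint kinase gene CHEK1 2.90-fold. The 29 genes of other DNA repair pathways had a median of -0.65 at percentile 0.30, with 5 at least 2-fold lower and 4 higher. Over the mean of members in place of the median this list was no longer outside the random range, at percentile 7.99. PARP1, which senses strand breaks, was 6.20-fold lower, LIG3 2.77-fold, NTHL1 2.70-fold and POLB 2.39-fold. The 6 probe sets of LIG3 ran from -2.07 to 0.84 on the log2 scale, and the gene was at -0.98, under 2-fold, in an alternative. The 4 higher members, named after their values were seen, were LIG4 (4.01-fold), ERCC1 (2.99-fold), MLH3 (2.82-fold) and ERCC5 (2.22-fold). The 9p21 genes, with a median at least 7.96-fold lower, differed in the same direction on these arrays.

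The medians of 3 lists of regulators around the division cycle lay inside the random range in the main setting. Of 28 p53 targets, 8 were at least 2-fold higher and 8 at least 2-fold lower, and the median of -0.04 lay at percentile 61.7. PLK2 and GDF15 were 6.47-fold and 5.62-fold higher and PMAIP1 was 3.17-fold lower. Among 13 members of the MuvB and DREAM complexes, which act with FOXM1 or before it on mitotic promoters, 5 were at least 2-fold lower and 1 higher (median -0.18, percentile 37.0), with LIN9 6.78-fold and E2F5 5.27-fold lower. Of 6 CDK inhibitor genes, 3 were at least 2-fold higher and 1 lower (median 0.72, percentile 93.7). Without _x_at and _s_at probe sets that median changed sign, to -0.22 at percentile 27.9, and with members above the floor on both arrays it was 1.11 at percentile 97.7, above the random range, each over 4 genes. CDKN1A was 2.66-fold higher.

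The genes linked to FOXM1 in earlier work, fixed without regard to their values, gave a mixed picture. Of 19 measured, 3 were at least 2-fold lower, 4 at least 2-fold higher and 12 differed by less. SKP2, a ubiquitin ligase subunit that targets CDKN1B, was 3.75-fold lower, although its 3 probe sets spread over an SD of 1.29 on the log2 scale. The mitotic kinase gene AURKB was 2.06-fold lower and the stem cell factor gene SOX2 at least 8.75-fold lower. The 3 probe sets of SOX2 had an SD of 1.77, and their median of -0.55 was under 2-fold. MMP2, a gelatinase, was 10.7-fold higher, VEGFA, a vascular growth factor, 5.07-fold, the cyclin gene CCND1 4.35-fold and CDKN1A, as above, 2.66-fold. The log2 differences of the mitotic genes CCNB1, PLK1, CDC25B, BIRC5 and CENPF were -0.06, -0.26, -0.30, -0.54 and -0.59. CKS1B, MYC, CTNNB1, STAT3, MELK, ADAM17 and CDKN1B gave -0.13, -0.28, -0.21, -0.01, 0.07, 0.31 and 0.34.

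Inflammatory and secretory genes were higher as a group on the array labelled FOXM1 siRNA. Of 28 detected members, 24 were at least 2-fold higher and none lower, with a median log2 difference of 3.23 (9.35-fold) above all 10000 random lists. Besides CSF3 and IL1B, the chemokine gene CCL20 was at least 17.9-fold higher and the growth factor binding protein gene IGFBP7 17.6-fold. Of 35 interferon-stimulated genes, 23 were at least 2-fold higher and 1 lower, with a median of 1.26 (2.39-fold) above all random lists. IFI44 was 16.4-fold higher, SAMD9 11.6-fold, the ubiquitin-conjugating enzyme gene UBE2L6 11.0-fold and the immunoproteasome gene PSMB9 10.8-fold. The other probe set of IFI44 gave a log2 difference of 2.15. Of 26 immediate early genes, 14 were at least 2-fold higher and 1 lower (median 1.06, above all random lists). The AP-1 subunit gene FOSL1 was 24.1-fold, FOSL2 9.43-fold, CCN2 6.14-fold and IER3 6.01-fold higher. On the same arrays the 9p21 genes were lower by the values above, while the 3' to 5' signal ratio of the ACTB control was 6.79 on the array labelled non-target siRNA and 4.21 on the other, and that of GAPDH 1.26 and 1.09.

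**Figure D2:**
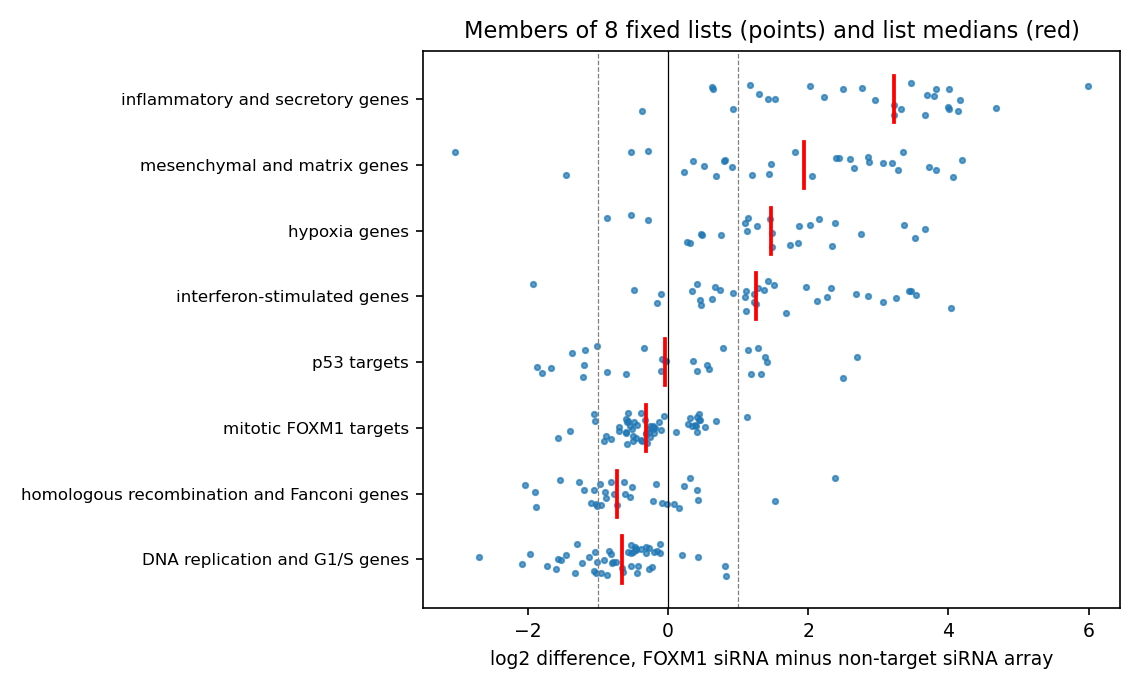
Log2 difference (FOXM1 siRNA minus non-target siRNA array, x axis) of each detected member of 8 fixed gene lists, 1 blue point per gene, with the list median as a red bar and dashed lines at a 2-fold difference. Most inflammatory and secretory genes (24 of 28) lie beyond 2-fold on the higher side, whereas 51 of 56 mitotic genes lie between the dashed lines.

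Matrix, invasion and vascular genes were also higher on the array labelled FOXM1 siRNA. Of 30 mesenchymal and matrix genes, 19 were at least 2-fold higher and 2 lower (median 1.93, 3.82-fold). The 2 lower members, named after their values were seen, were the collagen genes COL4A1 (-3.04) and COL4A2 (-1.45, log2 differences). COL6A3 was 18.2-fold higher, COL1A2 16.8-fold, tenascin C (TNC) 14.1-fold and the hyaluronan receptor gene CD44 13.2-fold, the last with an SD of 0.83 over 10 probe sets. Of 22 matrix proteases and inhibitors, 16 were higher and 1 lower (median 2.05, 4.13-fold). The urokinase gene PLAU was 15.7-fold higher, the collagenase gene MMP1 14.2-fold and TIMP4 at least 13.9-fold. Of 17 genes in the list of angiogenic factors, which also holds the angiogenesis inhibitors THBS1 and THBS2, 12 were higher and none lower (median 1.89, 3.70-fold), among them THBS2 at least 17.1-fold, NRP2 13.0-fold, NRP1 8.64-fold and HGF 7.58-fold. These 3 medians lay above all random lists. Of 19 TGF-beta targets, 10 were higher and 4 lower (median 1.10, percentile 99.99), with TGFB2 11.3-fold, LTBP2 9.88-fold and TGFBI 6.82-fold higher. The 4 lower members, named after their values were seen, were TSPAN2 (at most -2.32), SMAD6 (-1.44), ID2 (-1.03) and SKI (-1.01, log2 differences). Of 20 genes of the receptor tyrosine kinase pathway, 9 were higher and 4 lower (median 0.67, percentile 99.4). DUSP6, a feedback phosphatase of ERK, was 18.9-fold, the receptor genes AXL and EGFR 16.7-fold and 7.65-fold and SPRY2 4.24-fold higher. Other receptor genes of the list, named after their values were seen, were lower, with log2 differences of -4.03 for FGFR3, -2.32 for FGFR2, at most -2.27 for ERBB2 and -1.56 for IGF1R. With the median of a gene's probe sets, or the mean over list members, this list lay inside the random range at percentile 97.3.

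Genes of hypoxia and sugar metabolism were higher as well. Of 26 hypoxia genes, 18 were at least 2-fold higher and none lower (median 1.47, 2.77-fold, above all random lists). The carbonic anhydrase gene CA12 was 12.7-fold higher, ENO2 11.5-fold, the lipoprotein lipase inhibitor gene ANGPTL4 10.3-fold and the prolyl hydroxylase gene P4HA2 6.76-fold. Of 17 glycolysis genes, 6 were higher and none lower (median 0.66, percentile 99.8), among them ALDOC 4.66-fold and PFKP 4.45-fold. HK2 was 2.80-fold higher in its brightest probe set, but the median over its 3 probe sets was -0.37.

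Stress and organelle lists gave a mixed picture. Of 25 autophagy and lysosome genes, 10 were at least 2-fold higher and none lower (median 0.69, percentile 99.97), with WIPI1 11.3-fold and the lysosomal protease genes CTSB and CTSD 5.45-fold and 3.58-fold and the cholesterol transporter gene NPC1 3.24-fold higher. Of 30 unfolded protein and ATF4 response genes, 7 were higher, 1 lower and 22 under 2-fold (median 0.36, percentile 99.3), with DDIT3 6.25-fold, PPP1R15A 5.21-fold, CEBPB 4.13-fold and VLDLR 3.14-fold higher. Without probe sets that can match several transcripts this median lay at percentile 94.2, inside the random range. The medians of 14 heat shock genes (0.35, percentile 93.9), 20 oxidative stress defence genes (0.11, percentile 81.0) and 26 apoptosis regulators (0.29, percentile 94.1) lay inside the random range. So did those of 18 cholesterol synthesis and uptake genes (-0.37, percentile 14.9) and 20 Wnt targets (-0.27, percentile 8.61). The cholesterol median changed sign without _x_at and _s_at probe sets, to 0.32 at percentile 91.0. Single members stood apart: NQO1 was 9.14-fold and HMOX1 4.90-fold higher, HSPB1 5.35-fold and CRYAB 4.21-fold higher, INSIG1 5.27-fold higher and SC5D 6.51-fold lower, APAF1 3.66-fold and PMAIP1 3.17-fold lower, and SOX4 9.13-fold lower.

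The ribosomal protein and oxidative phosphorylation lists lay close to 0. None of 34 cytosolic ribosomal protein genes differed by 2-fold (median 0.01, percentile 55.0), and RPL18 and RPS3, the furthest, were 1.65-fold and 1.57-fold lower. Of 41 oxidative phosphorylation subunits, 2 were at least 2-fold lower (NDUFB10 2.26-fold and SDHD 2.01-fold) and none higher (median -0.15, percentile 17.8). Among 12 small RNA pathway genes 3 were lower (median -0.70, percentile 3.78), with the nuclear export factor gene XPO5 5.25-fold and TNRC6C 2.59-fold lower. The other probe set of TNRC6C gave a log2 difference of 0.05. The list of other forkhead genes had a median of -0.18 over 20 members (percentile 23.8), of which FOXF2 and FOXF1 were 31.0-fold and 7.35-fold lower. It also holds FOXRED1 (log2 difference -0.85), which is not a forkhead gene.

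Markers of neural and other cell types moved in both directions. Of 20 neural stem and progenitor genes, 6 were at least 2-fold lower and 2 higher (median 0.02, percentile 44.8), with the Notch target gene HES1 12.3-fold and the transcription factor gene POU3F2 12.1-fold lower. With the mean over members this list was at -0.57, percentile 1.01, below the random range. Of 8 astrocyte markers, FGFR3 was 16.3-fold lower and ALDOC 4.66-fold higher (median 0.43, percentile 89.4). Of 9 neuron markers, SNAP25 was 18.4-fold and GAP43 11.7-fold higher (median -0.01, percentile 49.2), the latter with an SD of 1.62 over 3 probe sets. Their lowest probe sets gave log2 differences of 2.66 and 0.48. With the mean over members the neuron list was at 1.02, percentile 97.73, above the random range. Of 9 leukocyte markers, HLA-DRA and CD74 were 44.7-fold and at least 13.3-fold higher, and the median of 0.48 lay at percentile 81.1. All 9 lay above 0. Matched random lists also had a median above 0, at 0.19. The floor is higher on the array labelled FOXM1 siRNA, which lifts the differences of dim genes. With a common floor the median of the leukocyte list was 0.27 at percentile 74.6. This list lay above the random range with the stricter floor (1.69 over 4 genes, percentile 99.75) and with the mean over members (1.40, percentile 99.89). Of 6 epithelial markers, KRT18 was 6.99-fold lower and CLDN7 at least 1.78-fold higher (median 0.36, percentile 69.8, but -1.27 over 2 genes with the stricter floor). Of the endothelial and oligodendrocyte lists only 4 and 3 members were detected, with medians of 0.91 and 1.59.

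**Figure D3:**
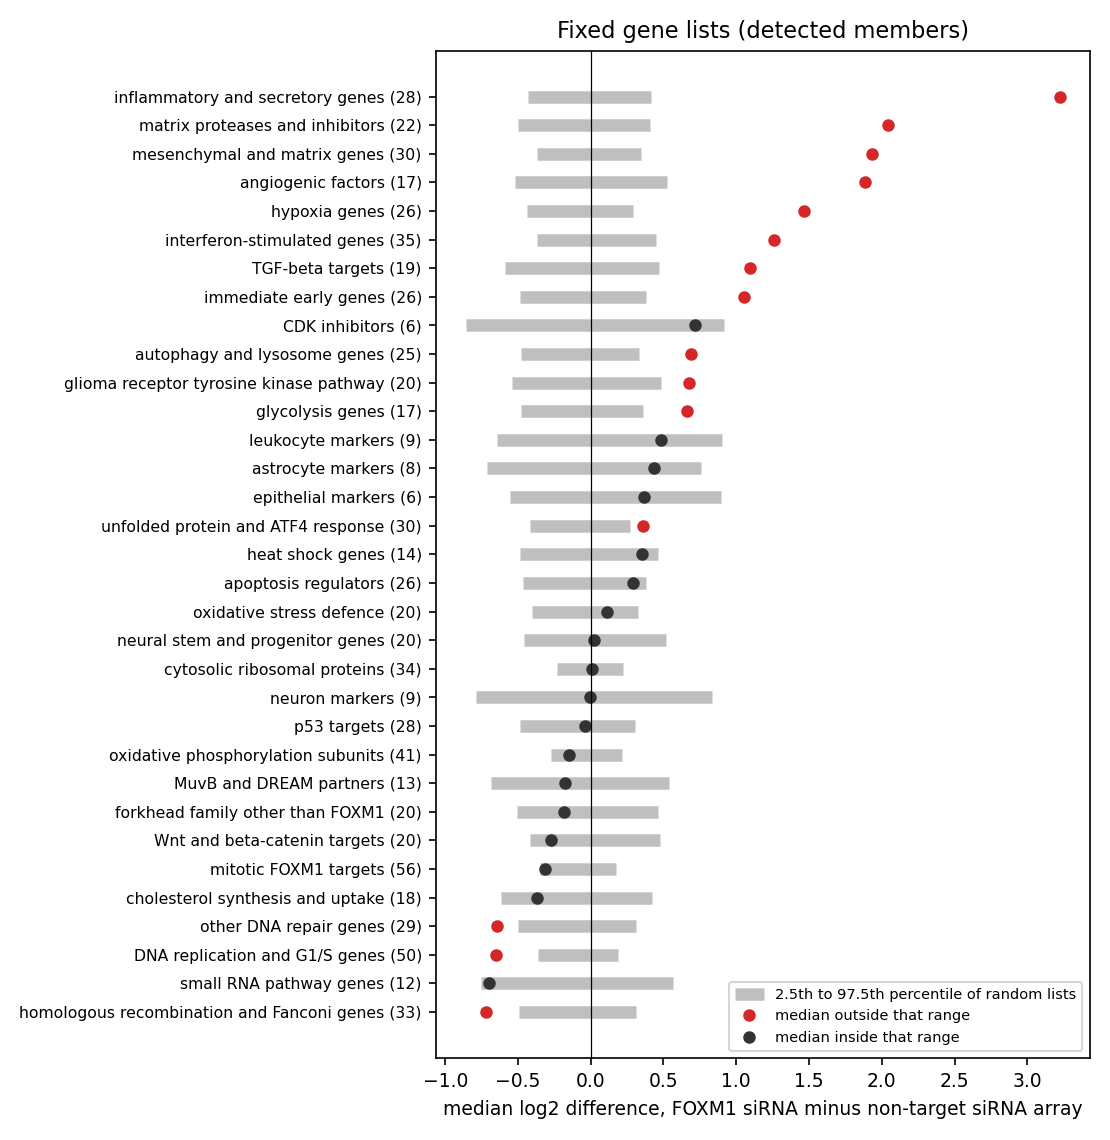
Median log2 difference (FOXM1 siRNA minus non-target siRNA array, x axis) of the 33 fixed lists with at least 5 detected members (number of members in brackets), over the central 95% of 10000 random lists of the same size matched on signal (grey bars). Red medians lie outside that range, 12 of them above it and 3 below it. For lists of genes drawn at random 1.65 would lie outside. The fixed lists overlap and their members can vary together, so that number is no rate of false calls here.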

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

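Both flags below came from probe sets outside the gene comparison, and all tests below except that of genes neighbouring on a chromosome were chosen or reworded after the results were seen; that of probe noise had first been written, with the same bounds, for probe noise or uneven RNA quality together. Of 13522 probe sets with no single gene symbol, 5673 (42.0%) lay above the floor on at least 1 array. Among these, 662 were at least 2-fold higher and 555 at least 2-fold lower on the array labelled FOXM1 siRNA, together 21.5%. The share was 31.4% of the genes compared, but there only the brightest probe set of each gene counts. The 2 shares are therefore not on like units.

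The first pattern is the breadth of the difference, 4350 genes at 2-fold or more, beside a FOXM1 transcript that differed by 1.13-fold. The tables argue against the authors' scaling, which applies 1 factor per array, as its source: among the 11395 genes above the floor on both arrays, 3433 differed by 2-fold or more, and no single factor of up to 4-fold between the arrays brought that count below 3408. They also argue against probe noise, since other probe sets of the same genes went the same way with a lower 95% bound of 89.1%. Another explanation is that the 2 arrays hold cells with different genomes, such as another line or another stock. It predicted that genes far apart on a chromosome would shift together, and log2 differences of genes 20 to 40 places apart correlated at 0.032, above the highest of 1000 shuffled gene orders (0.0069); in the lowest run of 51 genes, around TGFBR3, the median was -1.43 with 31 genes at least 2-fold lower, where the lowest run in 200 shuffled orders was -0.75. The highest run, centred on COL4A1, which itself was at -3.04, had a median of 0.92, where the highest in shuffled orders was 0.75. Adjacent genes correlated at 0.17. Copy number differences would give such a pattern. Shuffling also breaks up long domains of co-regulated genes, so the test cannot tell these from copy number differences. An effect of the siRNA on transcription and uneven RNA quality also stay open. The 3' to 5' ratio of the ACTB control was 6.79 and 4.21 on the arrays labelled non-target and FOXM1 siRNA, and RNA quality can move all probe sets of a gene together.

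The second pattern is the 9p21 locus. U87 cells are known to lack CDKN2A, CDKN2B and MTAP through a homozygous deletion, so that RNA of U87 cells on both arrays would leave these genes at the floor on both. The test asked whether both arrays hold RNA of U87 cells with the same 9p21 deletion. In the brightest probe set of each, all 3 genes were instead more than 4 times above the floor on the array labelled non-target siRNA. They were at least 4-fold lower on the other, which argues against RNA of such cells on both arrays. The other probe set of CDKN2B lay below the floor on both arrays (51.7 and 66.7), as did a further one of CDKN2A and of MTAP. Their neighbours KLHL9, FOCAD and MLLT3, chosen after their values were seen, were 13.5-fold, 10.2-fold and at least 8.05-fold lower, while IFNA17 among them read 117 and 125. A mislabelled sample, a mixed culture or a stock without the deletion may lie behind the transcripts on the array labelled non-target siRNA; which of them was not tested, and exchanging the 2 labels would not remove these transcripts. On the array labelled FOXM1 siRNA, the brightest probe set of CDKN2A was also 5.41 times the floor and that of KLHL9 3.88 times, so a share of such RNA, or cross-matching probes, stays open for that array too.

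A further pattern is the small difference in FOXM1. Scaling as its source is argued against by the lowest value over the scaling alternatives, -0.48, which stayed above a 2-fold fall. Noise of a single probe set cannot be told apart from a 2-fold knockdown. Such a fall lies 1.78 SD of probe set noise below the measured value, and the gene has only 1 probe set here. Estimated from the median absolute deviation, that SD was 0.35. With it the fall would lie more SDs away, so the answer depends on the estimate. A larger fall would lie further below the measured value and was not tested. A knockdown of the protein, or a transcript that had recovered by 48 hours, might also leave this value and was not tested. If the arrays hold different cells, the FOXM1 difference would also hold the difference between those cells.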

How the results depend on the processing

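No replicate could be left out, since each group holds 1 array, and no count could be run without a doubted array. No paired analysis was possible because each group has 1 sample. The counts of genes at least 2-fold higher and lower became 4593 and 3799 with no floor and 3623 and 3714 at a 1.5-fold threshold, as more genes or smaller differences then count. With the hybridisation control scaling, added after seeing the data, 3200 genes were lower. That scaling also moved the medians of DNA replication (-0.96), homologous recombination (-1.03), mitotic (-0.62), p53 (-0.34) and interferon-stimulated genes (0.95), all by the same shift. Median centring gave -0.81 for DNA replication and -0.47 for mitotic genes, and a pseudocount of 50 gave 1.02 for interferon-stimulated genes. The agreement of probe sets of one gene was 93.1% in direction and 55.1% at 2-fold or more with the stricter floor, where dim probe sets drop out. HK2 changed sign with the median of its probe sets (-0.37). FOXM1 stayed between -0.48 and -0.08 in all 9 alternatives run; without _x_at and _s_at probe sets it has no value. Of 15 lists outside the random range, 12 stayed outside it on the same side in all 12 alternatives; the receptor tyrosine kinase, other DNA repair and unfolded protein lists did not. Inside the range in the main setting but outside it in at least 1 alternative were the mitotic list (percentile 1.37 without _x_at and _s_at probe sets), small RNA, CDK inhibitor, leukocyte, neural stem and neuron lists; the cause was not tested. Some medians inside the range changed sign. Those of CDK inhibitors (-0.22) and cholesterol genes (0.32) did so without _x_at and _s_at probe sets. Epithelial markers did so with the stricter floor (-1.27, over 2 genes) or the mean over members, and astrocyte markers with no floor or the mean over members. The p53, ribosomal, oxidative stress, apoptosis, neural stem and neuron medians also changed sign in at least 1 alternative. The 9p21 median, a bound set by the floor, was -1.99 with the stricter floor. Some named genes had no value in an alternative, most often without _x_at and _s_at probe sets. Of 139 named genes other than FOXM1, 79 moved by less than the probe set SD in every alternative that gave them a value. Another 59 moved by more in at least 1. HK2, the remaining gene, was the only one at 2-fold or more to change sign. Among those under 2-fold, BIRC5 (up to 0.06), STAT3 (up to 0.28) and MELK (down to -0.24) also changed sign. AURKB, AUTS2, LIG3, NUP62CL, SDHD, SOX2 and TNRC6C fell under 2-fold in at least 1 alternative. Signals near the floor limit the folds of dim genes, which are bounds.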

Other observations

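Several gene families that were not fixed as lists differed as groups, though some members, such as HLA-DRA, ITGA5 and ITGB1, are in fixed lists. The families were chosen after their values were seen, from 233 symbol stems with at least 8 detected genes and 13 further name patterns. Large medians among them are therefore selected. Of 25 HOX genes, which mark position along the body axis and keep their pattern in cultured cells, 16 were at least 2-fold lower and 1 higher on the array labelled FOXM1 siRNA, with a median log2 difference of -1.23 below all 10000 random lists. All 7 metallothionein genes, which bind zinc and copper, were at least 2-fold higher (median 3.05), though their near-identical sequences can share probes. Of 11 MHC class II genes 8 were higher and none lower (median 2.06), and of 15 integrin subunits 10 were higher and 1 lower (median 2.06). Of 10 annexins 6 were higher and 1 lower (median 1.41, 0.69 in the lowest alternative). Of 12 MAGE genes 6 were higher and 1 lower (median 1.15, 0.12 in the lowest alternative). Zinc finger genes named ZNF leaned the other way, with 109 of 357 at least 2-fold lower and 22 higher (median -0.54). The direction of each of these medians was the same in all 10 alternatives run.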
